A study of Mus musculus with 2 samples.

How the data were processed

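The series holds 2 long-read RNA libraries of mouse adrenal gland from 10-day-old females of the strain B6CASTF1/J. Replicate numbers are those of the labels, which give 1 group. For each library the authors deposited a table of counts, whole reads per transcript model with no normalization, in which only models with at least 1 read are listed, and a gene model annotation with the coordinates of every model. Per the notes in the deposit, the assembly is mm10 and the annotation GENCODE M21, and the source column of the deposited annotation names TALON. Number of exons and length in bases of each model, also given in the deposited tables, were used to tell spliced from single-exon models. The sequencing platform, the aligner and the versions of the authors' tools are not given in the sources used here. Each library was processed on its own, so identifiers of unannotated models differ between libraries.

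The class of each model (annotated, incomplete splice match, unannotated combination of annotated splice sites, unannotated splice site, genomic, antisense, intergenic) was taken as the deposited tables give it. A gene's count was the sum over its models, and reads of the ERCC spike-ins (2.23 and 2.09% of all reads) were left out of genes and totals. The labels also name SIRV spike-ins, which were not analysed here. CPM was computed from the remaining 593165 and 772154 reads. The depth sets a limit of 5.06 and 3.89 CPM for a gene with 0 reads (3 counts). Spliced models were matched between libraries by identical chromosome, strand and introns; unannotated single-exon models of a gene were pooled as single-exon reads. Reads of overlapping single-exon models are given in the deposit under 1 model, so model ends are not the ends of each read. The genome sequence was not used, so splice motifs were not examined.

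With 1 group there was no test between conditions; tests compare the reads of the 2 libraries. For genes this was a two-sided exact binomial test against the share of total reads, with Benjamini-Hochberg adjustment over 10567 genes with 10 or more reads summed, called at an adjusted p below 0.05 and a ratio of at least 2-fold (pseudocount 0.5 reads). Counts adjusted over the list alone used the same test with adjustment over the tested members of a list. Folds against 0 reads, given as at least, are bounds computed with 3 reads in the library without reads and with the other count taken as exact. Exact 95% lower limits of the ratio are smaller, such as 41.3 beside 51.2 for Slc34a1 and 26.2 beside 33 for Myh7. Folds with few reads carry a 95% counting interval. For transcripts it was a two-sided Fisher's exact test of the main transcript against all other reads of the gene, in genes with at least 50 reads in each library, called at an adjusted p below 0.05 and 10 percentage points. Single shares have exact Clopper-Pearson intervals. The spread between libraries is the square root of edgeR's common dispersion (estimateDisp, TMM, intercept only). Gene lists were set beside 10000 random lists of the same size matched on expression, as a description of these libraries, using members with at least 5 reads summed.

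The tests, the rule for named genes, 22 gene lists and most alternatives were fixed before the data were examined. The lists were steroidogenic, zona glomerulosa, zona fasciculata, X-zone, chromaffin, capsule and fibroblast, endothelial, macrophage and leukocyte, erythroid, Schwann and glia, adipose tissue, kidney, liver, smooth muscle and pericyte, cholesterol synthesis and uptake, proliferation, immediate early and stress, imprinted, antioxidant, mitochondrially encoded, cytosolic ribosomal protein, and Y-linked with X-inactivation genes. A further 8 lists were written after the first results were seen: second lists of liver, kidney and brown fat, and skeletal muscle, muscle myosins, brain, testis and heart. Named genes are the 20 with the highest mean CPM outside ribosomal and mitochondrially encoded genes, list members (all of the steroidogenic, zone and chromaffin lists), the 10 largest folds in each direction among called genes, genes of a transcript list with 50 reads in each library, the 10 most abundant unannotated spliced models, the 10 largest differences in main transcript share among called genes, the 5 spliced intergenic loci with most reads in both libraries, and mitochondrial, Xist and Y-linked genes. Genes named outside the rule are said to be so. A few genes that the rule would name are not reported here.

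The gene tests, the dispersion, the list comparison and the transcript test were tested on simulated data; model matching, exon skipping and the ratio of lists were not simulated. In libraries with counting noise only and 50 changed genes per fold size, the binomial test recovered 94% of genes changed 3-fold and 100% of those changed 5, 10 and 20-fold, and called 5 unchanged genes. With no changed gene and the spread of the genes, estimated from the same 2 libraries, it called a median of 539.5 and at most 578 genes, and with the spread of the spike-ins a median of 0 and at most 2. The negative binomial test, simulated after the first results were seen with the spread of the genes, recovered 2, 8, 80 and 96% of genes changed 3, 5, 10 and 20-fold and called 0 unchanged genes. The dispersion step returned 0.248 for a simulated coefficient of variation of 0.25. A list of 15 genes shifted by 1 on the log2 scale gave a median of 0.92 at the 100th percentile, and an unshifted one gave -0.29 at the 7.35th. With counting noise only, the transcript test recovered 93.5% of 200 genes with the main share lowered by 30 points and called 5 unchanged genes. Spread of transcript shares between libraries was not simulated, so these 5 do not measure false calls in the real libraries. The single-exon share of Cyp11a1 was first set against all 115 spliced genes with at least 500 reads in each library (98.3th percentile), and then, since shares rise with last exon length, against 3 sets matched on that length; both steps followed the sight of its values. Alternatives varied the read minimum, the scaling, the fold minimum, the noise model, the classes of models counted, the match rule, the share that counts and the members of lists, and left out each replicate in turn. Used were R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 (median-of-ratios size factors), and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.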

Results

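Long-read RNA sequencing, in which each read is meant to cover most of an RNA molecule, was applied to adrenal glands of 10-day-old female B6CASTF1/J mice, the first-generation offspring of C57BL/6J and CAST parents. The labels put both libraries in 1 group of 2 biological replicates and name no treatment, other tissue or other age, so the series describes the gland and gives no contrast between conditions. Replicate 1 held 606677 reads on 103386 transcript models and replicate 2 held 788654 reads on 100292 models, of which 13512 and 16500 reads lay on ERCC spike-ins. The remaining 593165 and 772154 reads are the totals behind every value given as CPM, counts scaled to library total. A gene with 0 reads could thus still reach 5.06 CPM in replicate 1 and 3.89 CPM in replicate 2 (3 counts of each total). Annotated genes took 92.8% of the reads of replicate 1 and 94.9% of those of replicate 2, and 9615 genes had at least 5 reads in each library. Intervals and limits cover counting error only, since reads without stated molecular identifiers are not independent molecules. All coordinates are on mm10, and values are means ± SD over the 2 libraries unless a replicate is named. The library texts of both replicates name animal 03, while the biosample texts name animal 03 for replicate 1 and 04 for replicate 2. Whether the libraries come from 1 or 2 animals is thus open, and with it whether n = 2 and the SD cover differences between animals.

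Genes of steroid synthesis were the most abundant of the adrenal lists by summed CPM. The 18 members of the steroidogenic list were detected with at least 5 reads in each library and together reached 21193 ± 3340.2 CPM (n = 2), led by Cyp11a1, which cleaves the side chain of cholesterol. Cyp11a1 (ENSMUSG00000032323.13, chromosome 9, 58006411 to 58027023) stood at 7715 ± 1328 CPM, the highest mean of all genes that are neither ribosomal nor mitochondrially encoded. That rank counts its single-exon reads, whose origin is not settled and which were 57.6 and 61.1% of its reads in replicates 1 and 2. Cyp21a1, the steroid 21-hydroxylase (ENSMUSG00000024365.9, chromosome 17, 34801348 to 34804561), had 4321 ± 499 CPM. Hsd3b1 (ENSMUSG00000027871.16, chromosome 3, 98852194 to 98859794) had 2895 ± 316 CPM and Cyp11b1, which makes corticosterone (ENSMUSG00000075604.5, chromosome 15, 74834125 to 74841643), had 2258 ± 166 CPM. Star, which carries cholesterol into mitochondria (ENSMUSG00000031574.8, chromosome 8, 25806555 to 25815982), had 1379.9 ± 418 CPM. Of the remaining members, Fdx1 had 556 CPM, Tspo 396 CPM, Scarb1 312 CPM, Fdxr 306 CPM, Nr5a1 and Akr1b7 228 CPM each, Mrap 225 CPM, Por 135 CPM and Soat1 121 CPM. Fdps, Nr0b1, Mc2r and Npc1 lay between 12.3 and 38.8 CPM. Cyp21a1 has a pseudogene copy and Cyp11b1 a close paralog, so their reads are uncertain to the extent that the counting could split them.

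The chromaffin list, genes of the catecholamine-making medulla, was detected in full: all 26 members had at least 5 reads in each library, with a sum of 7045 ± 582 CPM (n = 2). The granule proteins Chgb (ENSMUSG00000027350.8, chromosome 2, 132781278 to 132795079) and Chga (ENSMUSG00000021194.6, chromosome 12, 102554969 to 102565028) led it with 1875 ± 101 and 1712 ± 166 CPM. Th, the first enzyme of catecholamine synthesis (ENSMUSG00000000214.11, chromosome 7, 142892752 to 142931128), had 943 ± 6.95 CPM, and Pnmt, which makes adrenaline (ENSMUSG00000038216.7, chromosome 11, 98386450 to 98388181), had 441 ± 169 CPM. Scg2 had 567 CPM, Npy 393 CPM, Cyb561 278 CPM, Dbh 177 CPM and Pcsk1n 154 CPM. Uchl1, Syp, Resp18, Stmn2, Scg5, Slc18a2, Snap25, Ddc, Gata3, Scg3, Phox2a, Cartpt, Hand2, Pcsk2, Slc18a1 and Pcsk1 lay between 12.2 and 61.3 CPM. Reads of the chromaffin list divided by those of the steroidogenic list gave 0.352 in replicate 1 (3935 over 11170 reads, 95% exact interval 0.340 to 0.365) and 0.317 in replicate 2 (5758 over 18188 reads, 0.307 to 0.326), mean 0.334 ± 0.0252. The ratios of the 2 libraries differed beyond counting error (Fisher's exact test, two-sided, p = 8.6e-06), which compares 2 libraries and not conditions. The ratio depends on how it is formed: its mean was 0.162 from median CPM, 0.503 with annotated transcript models alone, and 0.525 without Cyp11a1, an alternative added after the data were seen.

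Markers of the cortical zones differed widely in level. The zona glomerulosa list, the aldosterone-making outer zone, summed to 1878 ± 43.3 CPM, with 10 of 12 members at 5 or more reads in each library. Kcnk3, a potassium channel also counted in the second brown fat list, held most of it at 1211 ± 96.5 CPM, followed by Dab2 at 190.3 CPM, the aldosterone synthase Cyp11b2 (ENSMUSG00000022589.7, chromosome 15, 74851010 to 74856318) at 181 ± 41.9 CPM and Wnt4 at 131 CPM. Agtr1a had 57.7 CPM, Hsd3b6 31.5 CPM, Cacna1h 26.4 CPM, Vsnl1 13.2 CPM, Kcnk9 8.94 CPM, Agtr1b 8.75 CPM and Shh 5.57 CPM. Calb1 had 0 reads in replicate 1 and 20 in replicate 2. The zona fasciculata list summed to 3921 ± 586 CPM. It shares 4 of its 7 members with the steroidogenic list, Abcb1b with the X-zone list and Mgst1 with the antioxidant list, and its own member Cyp2f2 had 232 CPM, beside Mgst1 at 640.2 CPM and Abcb1b at 309 CPM. In the X-zone list, the transient inner cortical zone of young mice, Akr1c18 (ENSMUSG00000021214.14, chromosome 13, 4132615 to 4150654) had 413 CPM in replicate 1 and 895 CPM in replicate 2. Apart from Abcb1b, the other X-zone members were low: Sbsn had 15.4 CPM, Nr1h4 7.65 CPM, Thrb 6.16 CPM, Pik3c2g 2.33 CPM and Cyp17a1 0 and 3 reads. Akr1c18 was called higher in replicate 2, by 2.17-fold (exact binomial test, adjusted p = 1.6e-25), a call that was lost in the negative binomial test, which allows for spread between libraries. It was the 1 called gene of 4 tested in its list, over all genes and when adjusted over the list alone.

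Genes of fat tissue were abundant, and their order beside genes of steroid synthesis depends on the measure. The 9 members of the adipose tissue list were all detected and summed to 17456 ± 3202 CPM (n = 2), with 15191 against 18831 CPM for steroidogenic genes in replicate 1 and 19720.2 against 23555 CPM in replicate 2. The median CPM per member was higher for the adipose list (1019.95 and 1029.6 against 239 and 321), and so was the mean sum with annotated models alone (16234.5 against 15366 CPM). Fabp4, a fatty acid carrier of adipocytes (ENSMUSG00000062515.3, chromosome 3, 10204088 to 10208576), had 4540.2 ± 1772 CPM, Car3 4119 ± 216 CPM and Cidea 3633 ± 860.5 CPM. Ucp1, the heat-producing uncoupling protein of brown fat (chromosome 8, 83290352 to 83298452), had 2605 ± 584 CPM. Lpl had 1025 CPM, Cidec 438 CPM, Plin1 379 CPM, Adipoq 362 CPM and Cfd 354 CPM. None of the 9 passed the test between the libraries, 0 also when adjusted over the list alone. Fabp4 had 1950 against 4473 reads, a ratio of 1.76 (exact binomial test, adjusted p = 8.1e-100), and missed the call through the 2-fold minimum.

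Of the 20 genes with the highest mean CPM outside ribosomal and mitochondrially encoded genes, 17 did not pass the test between the libraries and 3 were higher in replicate 1. Besides the steroid and fat genes above they included genes of mitochondrial respiration, Atp5b (6948 ± 444 CPM), Cox4i1 (6727 ± 1659 CPM), Ndufa4 (3311 ± 1061 CPM), Uqcrc1 (3014 ± 186 CPM) and Atp5a1 (2939.6 ± 27.1 CPM). Gnas, which encodes the G protein subunit that couples the corticotropin receptor to cyclic AMP, had 2981 ± 115 CPM, Ubb 2819 ± 151 CPM, the globin Hba-a1 2635 ± 672 CPM and Aldoa 2596 ± 207 CPM. The 3 genes higher in replicate 1 were Trf, the plasma iron carrier transferrin, with 4167 against 584 reads (9.29-fold), the skeletal muscle actin Acta1 with 2911 against 975 reads (3.89-fold), and Apoe with 3646 against 1932 reads (2.46-fold). The negative binomial test called Trf and Acta1 but not Apoe. These folds have 95% counting intervals of 8.52 to 10.1, 3.61 to 4.18 and 2.32 to 2.6.

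**Figure D1:**
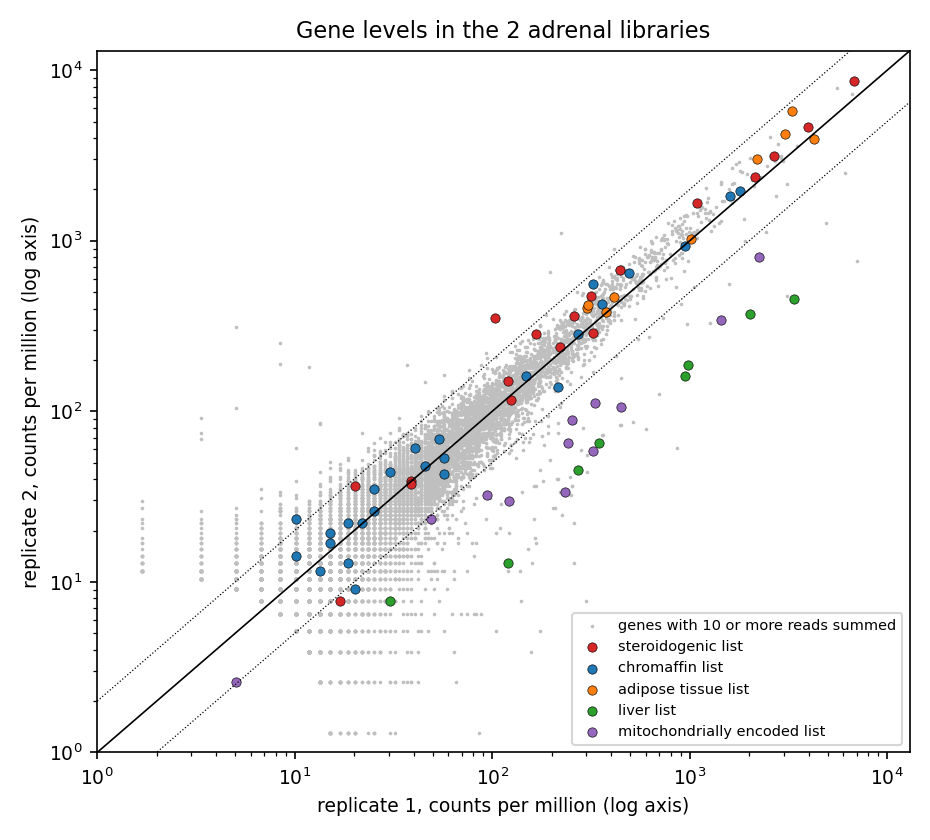
Level of each gene with 10 or more reads summed and at least 1 read in each library, as CPM on log axes, replicate 1 on the horizontal and replicate 2 on the vertical axis. The solid line marks equal levels and the dotted lines a 2-fold difference; coloured points are members of 5 gene lists. Of 8 liver and 11 mitochondrially encoded genes tested, 7 and 10 were called higher in replicate 1.

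The comparison of the 2 libraries asks how alike 2 samples of the same group were. Among the lists fixed before the data were examined, kidney and liver genes had the largest median differences. Of 10567 genes with 10 or more reads summed, 366 (3.46%) differed by at least 2-fold at an adjusted p under 0.05 in a two-sided exact binomial test on the reads, 273 of them higher in replicate 1 and 93 higher in replicate 2. That balance depends on the setting: without the fold minimum 336 were higher in replicate 1 and 381 in replicate 2, and with the reads of the steroidogenic list as totals, an alternative added after the data were seen, 588 and 56. Most of the called genes, 343, were protein coding, and 62 had mostly single-exon reads in the library where they were higher. Across genes, which are not independent replicates, levels of the libraries correlated with Pearson's r of 0.924 on the log2 scale and Spearman's rho of 0.902. The test takes in counting error only, while the libraries also differed by a biological coefficient of variation of 0.251. Its SE of 0.00657 was taken over blocks of genes and does not measure how uncertain a spread between 2 libraries is. That spread was estimated from the same 2 libraries, called genes included, and was 0.159 without the 500 genes with the largest fold, so it gives no independent measure of how many calls chance would give. A negative binomial exact test in edgeR with the dispersion of the 2 libraries called 132 genes, 94 of them higher in replicate 1; in simulated libraries it found 8% of genes changed 5-fold, so a call it did not keep is left open.

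Every tested member of the kidney list was higher in replicate 2. Replicate 1 had 0 reads on its 10 members, which allows up to 5.06 CPM, and replicate 2 had 532 reads (689 CPM), at least 136-fold more when measured against a limit of 3 counts over the list. All 8 tested members were called, 8 when adjusted over the list alone and 6 in the negative binomial test; Lrp2 had 2 reads and Pax2 0. Slc34a1, the phosphate carrier of the proximal tubule (ENSMUSG00000021490.11, chromosome 13, 55398187 to 55415592), had 0 against 200 reads, at least 51.2-fold higher. Miox (ENSMUSG00000022613.8, chromosome 15, 89334398 to 89337015) had 0 against 160 reads, at least 41-fold, and the water channel Aqp2 of the collecting duct (ENSMUSG00000023013.5, chromosome 15, 99579055 to 99584547) had 0 against 53 reads, at least 13.6-fold. The folds of Slc34a1, Miox and Aqp2 set 3 counts in place of 0, and their exact 95% lower limits are 41.3, 32.9 and 10.7. Umod, of the thick ascending limb, had 0 against 27 reads. The median log2 ratio of the list was 3.14 with absent reads set at 3 counts (5.75 with the pseudocount), above all 10000 random lists of matched expression. Kidney genes outside the list were also among the 10 largest folds in the same direction: S100g with 0 against 124 reads (at least 31.8-fold), Klk1 with 0 against 47 and Amn with 0 against 37. Fxyd2, also outside the list, had 3 against 241 reads (61.7-fold, 95% counting interval 20.9 to 301). The list member Cdh16, counted above, was among these folds too, with 0 against 44 reads. Gm45233, with 0 against 74 reads, consisted of single-exon reads alone.

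Liver genes were higher in replicate 1. The 8 members of the liver list took 8099 CPM in replicate 1 and 1304 CPM in replicate 2, a ratio of 6.21, and 7 of 8 were called (8 when adjusted over the list alone, 7 in the negative binomial test). Alb, the main plasma protein (ENSMUSG00000029368.10, chromosome 5, 90460897 to 90476602), had 2008 against 351 reads, 7.45-fold higher in replicate 1, and Apoa1 had 1197 against 286 reads, 5.45-fold higher (exact binomial test, adjusted p = 4.8e-187). Ttr, Apoa2, Fgb, Serpina1c and Cyp3a11 were higher by 5.19 to 9.24-fold, and Apoc3 had 18 against 6 reads without passing. The median log2 ratio of the list was -2.50, below all 10000 random lists. Serpina1c has near-identical copies, so its reads are uncertain. Afp, the fetal albumin relative (ENSMUSG00000054932.6, chromosome 5, 90490737 to 90508907), was among the 10 largest folds in this direction, with 177 against 6 reads (38.4-fold, interval 17.3 to 106), as was the complement protease gene Masp2 with 16 against 0 reads (at least 6.94-fold).

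Muscle genes were also higher in replicate 1. Myh7, the slow muscle and heart myosin (ENSMUSG00000053093.16, chromosome 14, 54970684 to 54994626), had 76 against 0 reads, at least 33-fold higher, Tnnc1 42 against 0 (at least 18.2-fold), Myl2 15 against 0 (at least 6.51-fold), Neb 14 against 0 (at least 6.07-fold) and Sln 93 against 3 (40.4-fold, interval 13.4 to 199). A list of 16 skeletal muscle genes, written after muscle genes had been seen among the differences, had 10 members called higher in replicate 1, 3 of them in the negative binomial test, and a median log2 ratio of -1.05. Its members Ckm, Tnnc2 and Mylpf had 1128 against 768, 937 against 428 and 621 against 415 reads, of which Tnnc2 was called. Of 6 muscle myosin genes, chosen after they were seen, Myh1 (510 against 47 reads), Myh2 (104 against 4) and Myh8 (83 against 6) were higher in replicate 1 together with Myh7, while Myh4 was higher in replicate 2 (5 against 147 reads), all 5 also in the negative binomial test. The other members of the 10 largest folds toward replicate 1 were Gm49450 (40 against 0 reads), Gm5096 (19 against 0) and the long noncoding RNA gene AC154200.1 (51 against 1), all of single-exon reads in that library.

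Genes of the mitochondrial genome were higher in replicate 1 and cytosolic ribosomal protein genes lay slightly toward replicate 2. The mitochondrially encoded list took 5793 CPM in replicate 1 and 1699 CPM in replicate 2. Of its 11 tested members 10 were called, 11 when adjusted over the list alone and 4 in the negative binomial test, with mt-Co1 at 1332 against 620 reads (2.8-fold), mt-Cytb at 853 against 266 (4.17-fold) and mt-Co2 at 139 against 26 (6.96-fold). Its median log2 ratio was -1.73, below all random lists. All mitochondrial reads were 0.593% of replicate 1 and 0.174% of replicate 2. Of 87 tested ribosomal protein genes 82 had the higher CPM in replicate 2, with a median log2 ratio of 0.41 that lay above all random lists and was 0.09 when the reads of the steroidogenic list served as totals. Among ribosomal genes 1 passed the test, also when adjusted over the list alone: Rpl3l, the striated muscle form, with 26 against 6 reads, higher in replicate 1, a call the negative binomial test did not keep.

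**Figure D2:**
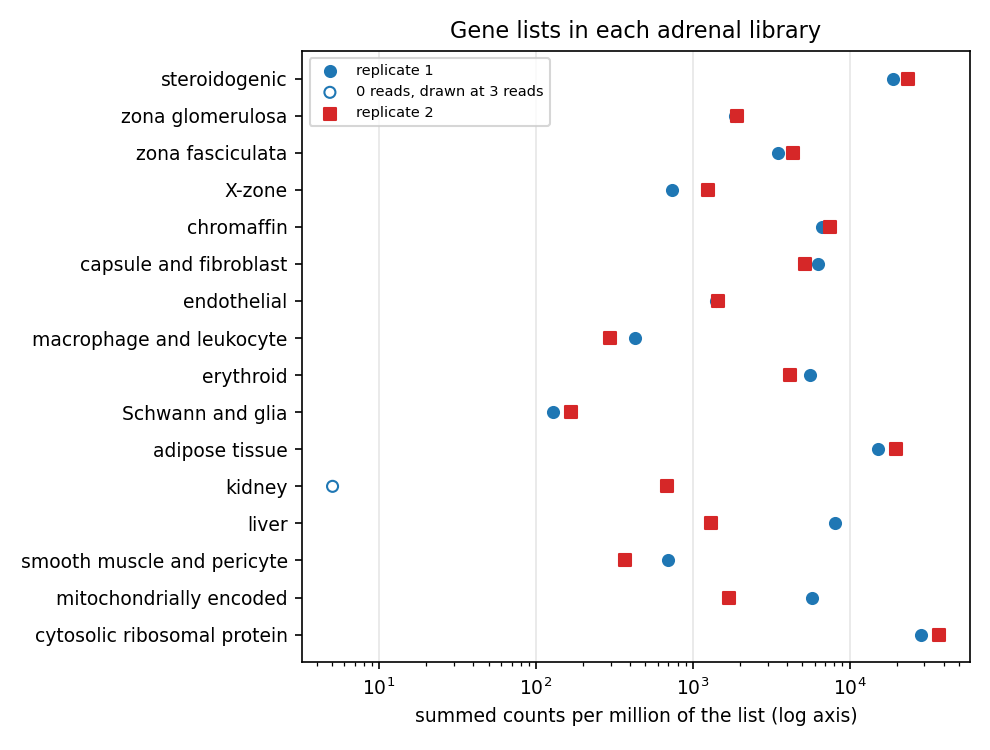
Summed level of 16 gene lists in each adrenal library, as CPM on a log axis, replicate 1 as circles and replicate 2 as squares. Kidney genes had 0 reads in replicate 1, drawn open at the limit of 3 reads (5.06 CPM), and 689 CPM in replicate 2; liver genes had 8099 and 1304 CPM, and steroidogenic genes 18831 and 23555 CPM.

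The lists of the adrenal itself separated the libraries less. In the steroidogenic list 1 of 18 members was called, Akr1b7, an aldose reductase of the cortex, with 61 against 273 reads, 3.44-fold higher in replicate 2 (exact binomial test, adjusted p = 4.1e-20), and again 1 when adjusted over the list alone. The negative binomial test did not call Akr1b7, with 0 calls in the steroidogenic and zona fasciculata lists. The same gene was the 1 call of 7 in the zona fasciculata list (1 when adjusted over the list alone). In the zona glomerulosa list Calb1 was called of 11 tested genes, at least 5.12-fold higher in replicate 2, again 1 when adjusted over the list alone and 1 in the negative binomial test. Calb1 is also a gene of the kidney's distal tubule. None of the 26 chromaffin genes was called, 0 also when adjusted over the list alone; among them Pnmt, at 191 against 433 reads, had the highest fold among members above 100 CPM, 1.74. The median log2 ratio was -0.12 for zona glomerulosa and 0.42 for adipose tissue genes, at the 29.5th and 97.3th percentile of random lists. The small medians of 4 lists change sign when the totals change: the median was 0.28 for steroidogenic, 0.12 for chromaffin, 0.30 for zona fasciculata and 0.02 for X-zone genes, and -0.04, -0.20, -0.02 and -0.31 with the reads of the steroidogenic list as totals. That scaling was added after the data were seen, shifts every gene alike by construction (the median of all genes from -0.04 to -0.36) and so says nothing on a list relative to other genes. The 4 lists lay at the 95.4th, 82.6th, 84.7th and 56.9th percentile of random lists.

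Among stromal and blood lists few genes were called. In the capsule and fibroblast list, summing to 5769 ± 785 CPM and led by Col3a1 (2269 ± 636 CPM), Sparc (1895 ± 102 CPM) and Col1a1 (873 ± 155 CPM), Fn1 was higher in replicate 1 (41 against 20 reads) and Tcf21 (16 against 54) and Mgp (15 against 50) were higher in replicate 2, 3 of 11 tested, the same number adjusted over the list alone, and 0 in the negative binomial test. The median log2 ratio of this list was -0.36, at the 1.18th percentile of random lists. Gli1 had 0 reads in both libraries. Endothelial genes (1427 ± 20.3 CPM; Cldn5 389 CPM, Plvap 216 CPM), macrophage and leukocyte genes (363 ± 95.2 CPM; Cd74 123 CPM, Lyz2 105 CPM), erythroid genes (4889 ± 991 CPM; Hba-a1, Hbb-bs 1213 CPM) and Schwann and glia genes (148 ± 27.5 CPM; S100b 69.3 CPM) had 0 called members of 12, 8, 5 and 4 tested, and 0 adjusted over the list alone. All 5 tested erythroid genes had the higher CPM in replicate 1 (median log2 ratio -0.50, at the 0.72th percentile of random lists). The alpha and beta globin genes have near-identical copies and their reads are uncertain between copies. In the smooth muscle and pericyte list Des, which striated muscle also makes, was the 1 call of 6 (269 against 80 reads, higher in replicate 1; 1 adjusted over the list alone and 1 in the negative binomial test).

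Lists of cell state gave the following counts. Of 18 cholesterol synthesis and uptake genes (1494 ± 48.2 CPM; Hmgcs1 319 CPM, Acat2 187 CPM) 0 were called and 1 when adjusted over the list alone. Of 12 proliferation genes (606 ± 25.3 CPM; Mcm2 131 CPM, Rrm2 91 CPM, Mki67 9.33 CPM) 0 were called, 0 also when adjusted over the list alone. In the immediate early and stress list (1684 ± 279 CPM) Junb (52 against 145 reads, 2.14-fold) and Nr4a1 (27 against 115 reads, 3.27-fold), genes induced by stimulation, were called higher in replicate 2, 2 of 11 tested, 2 adjusted over the list alone and 0 in the negative binomial test; the median log2 ratio of 0.54 lay at the 99.9th percentile. Hspa8 led this list at 1090.5 CPM, and Atf3 had 0 reads. In the imprinted list (5718 ± 668 CPM; Gnas 2981 CPM, Cdkn1c 853 CPM) H19 (553 against 123 reads, 5.85-fold) and Igf2 (42 against 23 reads, 2.38-fold) were higher in replicate 1, 2 of 19 tested and 2 adjusted over the list alone, while the negative binomial test kept H19 alone. Young liver and muscle express both genes, and 7 of 8 liver and 10 of 16 skeletal muscle genes were called higher in the same library. In the antioxidant list (6473 ± 1408 CPM; Prdx1 1061 CPM, Gpx4 1009 CPM) Gpx3, which the kidney secretes, had 132 against 858 reads, 4.99-fold higher in replicate 2, 1 call of 18 and 1 in the negative binomial test, and 2 when adjusted over the list alone, Gsta4 (13 against 40 reads) being the other. As a check of the labels, Xist had 18 and 37 reads and Tsix 16 and 22, while the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 reads in both libraries, as the labelled sex requires; 0 of the 2 tested genes was called, 0 adjusted over the list alone.

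Transcript models describe what the reads looked like. Annotated models held 68.8 ± 4.16% of the reads (n = 2), 65.9% in replicate 1 (95% exact Clopper-Pearson interval 65.8 to 66) and 71.8% in replicate 2 (71.7 to 71.9). Incomplete splice matches, models that hold part of an annotated intron chain, took 12.6 and 11.2%. Unannotated combinations of annotated splice sites took 4.35 and 4.02%, models with an unannotated splice site 3.27 and 3.20%, and genomic models, which lack the gene's splicing, 6.89 and 4.85%. Antisense and intergenic models took 6.17 and 4.23% and 0.841 and 0.712%. Single-exon reads were 20.4% of replicate 1 and 16.2% of replicate 2.

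Unannotated spliced models recurred between the libraries according to their depth. Each library was processed on its own, so models were matched by exact intron chain. Of models with unannotated splicing and at least 2 reads, 65.8 ± 5.66% had at least 1 read in the other library (69.8% of 4624 models of replicate 1 and 61.8% of 5953 of replicate 2). The share was 69.3 ± 5.21% for models that combine annotated splice sites, 59.7 ± 6.17% for those with an unannotated site, 92.1 ± 2.16% for annotated models and 69.5 ± 4.52% for incomplete splice matches. It was 24.4% from 1 read, 95.5% from 5 reads and 99.2% from 10 reads.

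**Figure D3:**
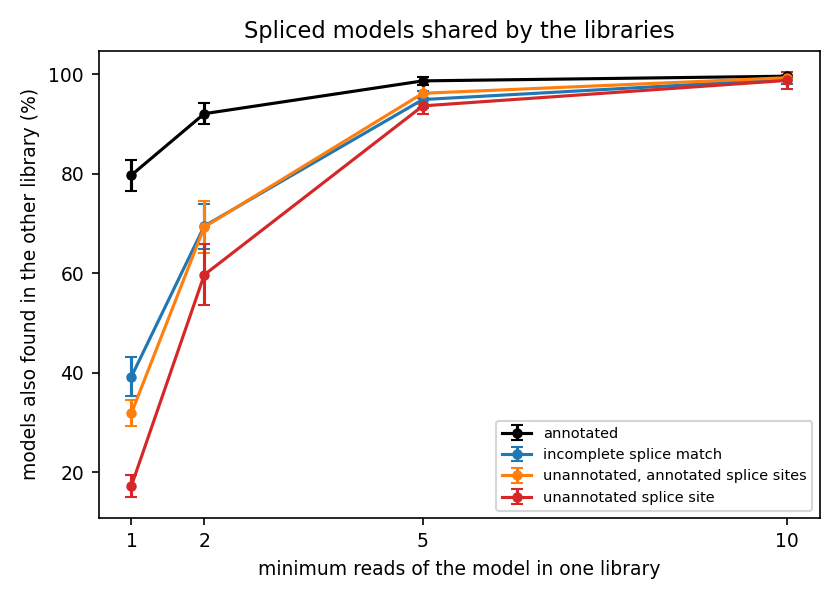
Share of spliced transcript models of one library that had at least 1 read with the same intron chain in the other, in percent, against the minimum reads of the model in the first library (1, 2, 5 and 10). Points are means and bars SD over the 2 directions; annotated models went from 79.8% at 1 read to 99.6% at 10, and models with an unannotated splice site from 17.3% to 98.8%.

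Most genes used an annotated main transcript. Of 2162 genes with at least 50 reads in each library, 1998 (92.4%) had an annotated main transcript, 71 had single-exon reads as the main form, 43 and 19 had an unannotated model with annotated and unannotated splice sites, and 31 an incomplete splice match. In 749 genes (34.6%, 95% exact interval 32.6 to 36.7) at least 2 transcripts each held more than 10% of the reads in both libraries. Of the 41 measured genes of the transcript list, 35 had an annotated main transcript. Star-201 held 68.2 ± 1.62% of the reads of Star, Cyp11b1-201 86.4 ± 0.657%, Cyp21a1-201 75.8 ± 2.82%, Th-201 87.8 ± 3.83%, Pnmt-201 88.2 ± 1.05%, Chga-201 75.7 ± 0.502% and Chgb-201 72.7 ± 0.878% (n = 2 each). Gnas-208 held 44.3 ± 0.938% of its gene, Sparc-201 33.4 ± 1.45%, Nr5a1-201 40 ± 7.59%, Myl6-201 50.2 ± 0.742% and Tpm1-205 86.2 ± 0.748%. The main form of Hsd3b1 was a 4-exon incomplete splice match with 66.7 ± 4.78%, and that of Cyb561 a 6-exon one with 54.5 ± 4.11%. Single-exon reads led Cyp11a1 (59.3 ± 2.48%), Meg3 (57.9 ± 5.43%) and Nnat (55.4 ± 3.78%), and Rps24 was led by a model with an unannotated splice site (28.5 ± 7.84%).

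The use of the main transcript differed between the libraries in 39 of the 2162 genes (two-sided Fisher's exact test, adjusted p under 0.05, at least 10 percentage points), 37 of them with the higher share in replicate 2. Without the minimum difference 79 genes passed. This test, too, takes in counting error only, and no alternative allowed for spread of transcript shares between libraries. Tpm3-201 of the tropomyosin gene Tpm3 (chromosome 3, 90072649 to 90100902) held 42.1% of 195 reads in replicate 1 and 84.1% of 164 reads in replicate 2. Another transcript of the gene, Tpm3-205, had 60 reads in replicate 1 and 1 in replicate 2. In replicate 1, 10 of 16 skeletal muscle genes were called higher, and whether RNA of muscle contributed to this shift in Tpm3 was not tested. Atp2a2-201 of the calcium pump Atp2a2 (chromosome 5, 122453513 to 122502225) held 33 and 67%, and a 22-exon unannotated model of its muscle relative Atp2a1 (chromosome 7, 126445858 to 126463108) held 58.4 and 84.1%. Slc25a25-203 held 34.6 and 70%, Sf3b3-201 47.5 and 75.8%, Tmem65-201 67.9 and 94.7%, Bap1-201 54.1 and 79.5%, Bin1-205 11.9 and 35.4% and Trim28-201 61 and 84.4%. In the opposite direction Cfl1-202 of cofilin (chromosome 19, 5490455 to 5495201) held 99.4% in replicate 1 and 64.2% in replicate 2. Single-exon reads of Cfl1 were 0 of 159 reads in replicate 1 and 128 of 386 in replicate 2, so the difference lay mainly in these reads. Across all 2162 genes the median share of the main transcript was 77.4% in replicate 1 and 81.3% in replicate 2, with 1521 genes higher in replicate 2 and 570 higher in replicate 1. With annotated models alone 3 genes differed, and without incomplete splice matches and genomic models 5, although these settings also leave fewer genes to test (1547 and 1749).

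The 10 most abundant unannotated spliced models in both libraries came from 9 genes, and 6 of them lacked a very short annotated exon. The leading model, 814 and 1262 reads of Oaz1 (chromosome 10, 80826656 to 80829290), held 93.7 and 95.5% of its gene and differed from Oaz1-207 by keeping an annotated intron of 1 base at 80828295; a model of Oaz2 (chromosome 9, 65668001 to 65690300) with 196 and 198 reads kept one of 1 base at 65686272. Oaz1 and Oaz2 encode antizymes, whose synthesis needs a ribosomal frameshift. An annotated intron of 1 base is a feature of the annotation, so both models are not read here as retaining a spliced intron. Both Atp2a1 models (844 and 727 reads; 382 and 48 reads) lacked the 18-base exon at 126462500 to 126462517, and the lower one also lacked a 42-base exon at 126446545 to 126446586. The model of Phb2 (231 and 327 reads; chromosome 6) lacked a 6-base exon at 124716425 to 124716430. The model of Idh3g (177 and 341 reads; chromosome X) lacked a 12-base exon at 73782298 to 73782309. The model of Mrpl33 (155 and 234 reads; chromosome 5) lacked a 19-base exon at 31614603 to 31614621. The model of Mpc1 (158 and 210 reads, chromosome 17) lacked a 4-base exon at 8296527 to 8296530. Its own intron ended at 8296534, so the annotated intron after that exon spans only a few bases. Mknk2 and Ctbp1 lie on the minus strand, and starts and ends here follow the direction of transcription. In Mknk2 (251 and 287 reads, chromosome 10) an intron at 80675941 to 80676122 started 42 bases from the annotated one. In Ctbp1 (138 and 204 reads, chromosome 5) an intron at 33248687 to 33249106 ended 3 bases from the annotated one.

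Outside the genes of the 12 most abundant unannotated models, a comparison added after these were seen, annotated internal exons of 20 bases or fewer were skipped by 64.7% of 1821 spanning reads in replicate 1 and 62% of 2148 in replicate 2 (23 exons). The shares were 2.60 and 2.89% for 705 exons of 21 to 50 bases and 0.327% in both libraries for 14740 longer exons. The 13-base exon of Cct6a (chromosome 5, 129794635 to 129794647) and the 8-base exons of Pitpna (chromosome 11, 75608107 to 75608114) and Pitpnb (chromosome 5, 111347120 to 111347127) were skipped by all spanning reads, and those of Capn2, Hacd1, Col6a1 and Suds3 by 98 to 99.5% on average. Other short exons were skipped almost fully between annotated splice sites: those of Tnni2 (109 of 109 and 75 of 75 reads, 3 and 1 at an unannotated site), Sept7 (88 of 88 and 95 of 96, 4 and 2), Immt (78 of 79 and 93 of 93, 4 and 6) and Uchl3 (51 of 52 and 68 of 68, 0 and 0). The 6-base exon of Cfl1 and the short exons of Ik and Parva were skipped by 0 spanning reads. These genes were chosen after their values were seen.

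**Figure D4:**
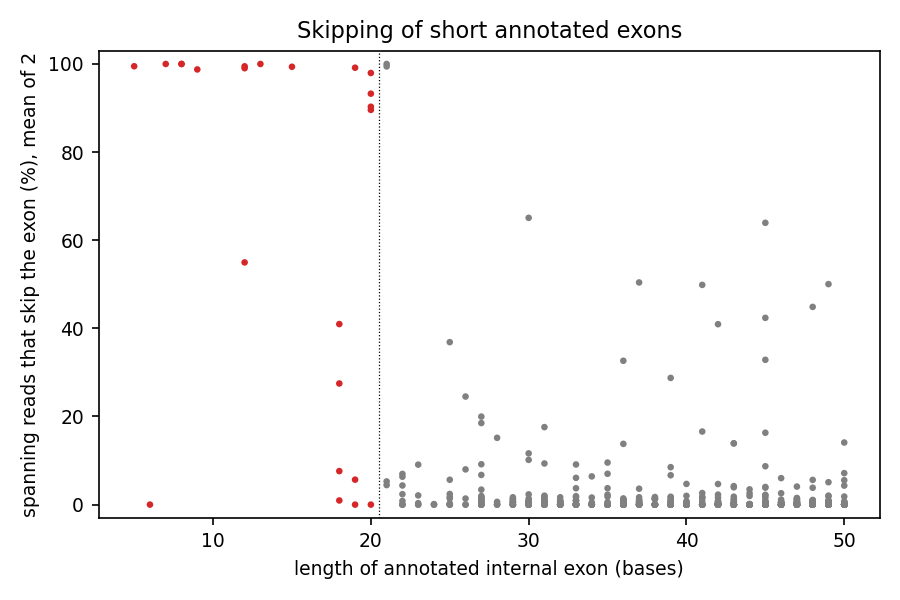
Percent of spanning reads that skip each annotated internal exon of 50 bases or fewer, as the mean of the 2 libraries, against exon length in bases, outside the genes of the 12 most abundant unannotated models. Red points left of the dotted line are the 23 exons of 20 bases or fewer, of which 17 were skipped by more than 20% of reads in each library, against 15 and 17 of the 705 exons of 21 to 50 bases (grey).

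Spliced intergenic models were few. Of 198 spliced intergenic models in replicate 1 and 269 in replicate 2, 30 had the same intron chain in both. The 5 with the most reads each had 2 exons: chromosome 2, 167847193 to 167847828 (4 and 18 reads; 84229 bases from Ptpn1, the nearest coding gene), chromosome 8, 126978047 to 126979382 (8 and 14 reads; 6976 bases from Rbm34), chromosome 13, 21812999 to 21820126 (6 and 9 reads; 852 bases from Hist1h4m), chromosome 11, 88890250 to 88896412 (6 and 6 reads; 25664 bases from Akap1) and chromosome 7, 48124177 to 48132212 (5 and 7 reads; 35771 bases from Mrgprb5).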

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

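The tests on Cyp11a1 were chosen after its values were seen; the tests on tissue genes and short exons were written before the results they measure. No biological explanation was tested, since the design gives 1 group.

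Signals outside the gene measurement stood above the limit that 0 reads allow. Antisense models held 6.17% of the reads of replicate 1 and 4.23% of those of replicate 2, and intergenic models 0.841 and 0.712%, of which 97.6 and 97.3% and 94.5 and 93.5% were single-exon. ERCC spike-ins took 2.23 and 2.09%, with a coefficient of variation of 0.0405 between the libraries over 32 spike-ins, beside 0.251 for genes. The largest antisense locus lay on chromosome 17, 39843013 to 39846245, opposite Gm26917, with 2364 and 1306 reads.

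Genes of liver, kidney and brown fat stood in both or in either library, and second lists of genes whose values had not been seen, Kcnk3 apart, bear on where they came from. Of 19 tested genes of the second liver list, 89.5% were higher in replicate 1 (13 called, 15 adjusted over the list alone, 12 in the negative binomial test; Rbp4 750 against 255 reads, Kng1 415 against 97, Serpina1b 307 against 67, but Apoc1 225 against 243), although 17 had at least 5 reads in both. Of 11 tested genes of the second kidney list, 81.8% were higher in replicate 2 (3 called, 5 adjusted over the list alone, 1 in the negative binomial test). Ggt1 had 0 against 23 reads and Slc22a8 1 against 21, while 5 of 19 members, such as Fbp1 with 81 against 132, had at least 5 reads in both. This list summed to 376 CPM in replicate 1 and 532 CPM in replicate 2, a ratio of 1.42, beside at least 136-fold for the first kidney list. Of the second brown fat list 86.7% of 15 members had at least 5 reads in each library, including Cox7a1 (630 against 1242), Pdk4 (354 against 580) and Kcnk3, also a member of the glomerulosa list. The same held for 1 of 10 brain, 1 of 10 heart and 0 of 10 testis genes, but also for 12 of 16 skeletal muscle genes. The median log2 ratio of the second brown fat list was 0.04. Of its 13 tested members 1 was called, higher in replicate 1 (1 adjusted over the list alone, 0 in the negative binomial test). The adipose tissue list lay toward replicate 2, with a median of 0.42 and 8 of 9 members higher there. Whether the amount of brown fat RNA differed between the libraries is thus open. These values are consistent with RNA of neighbouring liver, kidney and brown fat in the samples, with liver and kidney in differing amounts; RNA of muscle was not tested, and carry-over between libraries of other tissues and a real difference between the samples stay open.

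Single-exon reads of Cyp11a1 were 57.6% (95% exact interval 56 to 59.1) of its reads in replicate 1 and 61.1% (59.9 to 62.3) in replicate 2, while the annotated Cyp11a1-201 held 33.2 and 29.3%. Genomic DNA across the gene is argued against: at least 99.9% of the single-exon reads of each library lay on a model that ends within 50 bases of the 3' end, and 2 and 0 reads lay elsewhere in the gene, although the ends of a model are not those of each read. That model spanned 58023657 to 58027023 in replicate 1 and 58025078 to 58027023 in replicate 2, which reaches beyond the last exon of 330 bases. How many reads reached beyond that exon is not known, and a match on last exon length does not cover any that did. Shortening toward the 3' end that affects all genes alike cannot be told apart from a cause in this gene: single-exon shares rose with last exon length (Spearman's rho 0.568 and 0.616 over 114 spliced genes with at least 500 reads in each library), and Cyp11a1 was picked for its share. Its percentile was 97.3 among 73 genes with a last exon at least as long as its 330 bases, 96.5 among 57 within 2-fold of that length and 94.9 among 39 within 1.5-fold, all 3 sets compared after the values were seen; Slc25a5 (58.2 and 63.5%) alone lay above it, although the medians of the sets were far lower, 1.03 to 4.41%. Priming inside the transcript, partly spliced RNA of the last exons and a shorter transcript were not tested and stay open.

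Abundant unannotated models that lack a very short annotated exon made up 6 of the 10 most abundant unannotated spliced models. Those of Phb2 and Mpc1 skipped it between annotated splice sites, so the shares below at unannotated sites leave them unexplained. In Mpc1 the model's intron ended at 8296534, so the annotated intron after the exon spans only a few bases. The Mpc1 model is thus not a clear case of a skipped exon. Of reads that skip an exon of 20 bases or fewer outside those genes, at least 59.2% in each library (63.6% in replicate 2) did so at an unannotated splice site, against 9.24 and 8.32% for exons over 50 bases. This is consistent with reads aligned across exons too short to place. An allele of the CAST parent is argued against for exons that nearly all reads skipped at an unannotated site, such as those of Cct6a, Pitpna and Pitpnb. Of 15 exons with at least 1 such read in each library, 86.7% were skipped by over 75% of reads in both. By the same measure 0 were skipped by 35 to 65%, the range that 1 of 2 parental alleles would give. These shares count skipping at any site, and the exons of Tnni2, Sept7 and Immt were skipped mostly at annotated sites. The 20-base exon of Rps24 was skipped at an unannotated site by 33 of 72 and 39 of 90 reads, so an allele is not argued against there. True skipping stays open, above all for the exons of Tnni2, Sept7, Immt and Uchl3, which nearly all reads skipped between annotated sites (109 of 109 reads of Tnni2 in replicate 1, 3 at an unannotated site) and which the values at unannotated sites therefore leave unexplained.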

How the results depend on the processing

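Added after the data were seen were scaling by the steroidogenic reads, dropping the 500 genes with the largest fold, dropping genes of mostly single-exon reads, and dropping Cyp11a1. Of 414 alternative values, apart from those that leave out a library, 273 kept their call or stayed within the spread, the exact interval or, for counts of genes, 1.5 times the count, and 141 did not, and no called result changed direction. The cause was not tested, except that stricter minimums and fewer classes leave fewer genes and models by construction. Among the values that stayed, 100 gene levels and 22 list sums only left mitochondrial reads out of the total. These reads were 0.593 and 0.174% of replicates 1 and 2, so such values could hardly move. A further 22 list differences used TMM scaled totals, with factors of 1.01 and 0.988, which shift all genes alike. Such values say little on robustness. Genes detected numbered 4880 from 20 reads. The coefficient of variation was 0.234 with annotated models alone and 0.159 without the 500 genes with the largest fold. Genes that differ numbered 717 without the fold minimum, 238 with annotated models alone, 132 with the negative binomial test and 644 with steroidogenic reads as totals, against 366. The share of called genes higher in replicate 1 was 74.6%, and 64% with median-of-ratios factors, 91.3% with steroidogenic reads as totals and 46.9% without the fold minimum. The share of reads on annotated models was 79.7% for spliced models, 80.6% for models with 5 or more reads, and 65.9 to 71.8% when either library was left out. Recovery of unannotated spliced models was 24.4% from 1 read, 95.5% from 5, 99.2% from 10 and 0% by identifier, which carries the library's name. Differing transcript use held for 21 genes from 20 reads, 3 with annotated models alone and 5 without incomplete splice matches and genomic models, against 39. Genes with several transcripts were 32.4% from 100 reads, 16.5% with annotated models, 20.2% without incomplete splice matches and genomic models, 54.5% at a share of 5% and 15.2% at 20%. The ratio of medulla to cortex was 0.503 with annotated models, 0.385 without Chgb and Cyp11a1, 0.162 from median CPM, 0.525 without Cyp11a1, and 0.317 to 0.352 when either library was left out. Annotated models alone gave sums of 15366 CPM for steroidogenic and 7713 CPM for chromaffin genes, and leaving out either library gave 18831 to 23555, 6634 to 7457 and, for adipose genes, 15191 to 19720.2 CPM. With steroidogenic reads as totals the median log2 ratio of steroidogenic genes was -0.043, of chromaffin genes -0.20 and of adipose genes 0.0931, and with annotated models alone that of adipose genes was 0.40. Depth limits statements on genes under about 5 reads.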

Other observations

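No tests were run for the values below, and the genes were chosen after their values were seen. Genes with many single-exon reads beside Cyp11a1 included Apoe (44.4 and 46.2% of its reads), Kcnk3 (41.4 and 37.6%), Cidea (38.7 and 38.4%) and Idh3b (27.8 and 33.9%), all spliced genes with at least 500 reads in each library.

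Antisense reads also stood opposite Actb (408 and 482 reads), Tmem250-ps (250 and 364), Nfia (133 and 191) and Cdv3 (128 and 174) in replicates 1 and 2. Of 604 and 635 spliced antisense models, 84 had the same intron chain in both libraries.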
